A study of Danio rerio with 34 samples.

How the data were processed

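Whole zebrafish larvae of the wild-type AB strain were profiled for RNA on 34 one-colour microarrays. Per the labels' protocols, embryos aged 3 hours were placed at 35 to 40 per well in 4 mL of medium with 0.05% DMSO and a glucocorticoid or DMSO alone, the medium was renewed every 24 hours, and pools were collected at 5 days of age. The control group (DMSO) has 4 arrays and each of the 6 treated groups has 5: dexamethasone, prednisolone and triamcinolone, each at 5 and 50 nM. Per the labels' protocols, 200 ng of RNA with an integrity number above 8 was amplified and labelled with Cy3. The arrays were of Agilent's zebrafish design with 43803 spots besides 1417 control spots, and 4 arrays shared a slide where it was full.

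The authors deposited one scanner file per array and one table of their own values. Per the file headers, the scanner files were made by Agilent Feature Extraction 10.7.3.1 (10.7 per the submitters' processing notes), and the column used here is the background-corrected green processed signal, an intensity with no normalization between arrays. The authors' table of deposited values, on a log2 scale, holds 33738 probes and states neither its centring nor any adjustment. Each of its columns was set against the scanner values of the same array after centring each probe. Pearson's r across probes, which are not independent replicates, was 0.28 to 0.95, and 30 of 34 columns fitted their own array best. After both sides were centred within slides, r was 0.77 to 0.99 and 34 of 34 fitted their own array best. Column medians were -0.093 to 0.075. Whether the authors adjusted for the slide is not stated, so this table serves only as an alternative.

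For the main values, each array's log2 intensity was lowered by the log2 of that array's 75th percentile over all spots that are not controls. The 819 spots with an outlier mark were left out, none was saturated, and the 50 probes with several spots were averaged. A probe was kept when well above background on at least 3 control arrays or at least 4 arrays of a treated group, which left 38166 of 43603 probes. Probes were named by their RefSeq accession through the reference table, without version numbers. This gave 25978 probes exactly 1 symbol, 17625 no symbol and 0 several. Probes without a symbol kept the identifier of the array file. Each gene was represented by the detected probe with the highest mean over all arrays, which gave 24304 genes, 12702 of them with a symbol. The rule was checked against all detected probes of a gene, and disagreements are stated with the gene.

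All genes were fitted by limma 3.58.1 (R 4.3.3, statmod 1.5.0) with 7 group means, no covariates and all 34 arrays, giving 27 residual degrees of freedom and 3.06 prior degrees of freedom. The contrasts were each treated group against control, the mean of the 3 compounds at each dose against control, 50 against 5 nM within each compound, each pair of compounds at each dose, and the interaction of compound and dose. The Benjamini-Hochberg threshold was 0.05 for each contrast, tests were two-sided, and a gene past it is called here changed, risen or fallen. Log2 changes are given with their standard error. The mean over a fixed list of glucocorticoid receptor targets was compared by exact two-sided permutation tests of the arrays, adjusted over 15 comparisons. Gene lists, 27 in number with 1094 names, were tested by limma's camera with a preset correlation of 0.01, adjusted over 216 tests (27 lists in 8 contrasts), and again with the correlation estimated. For camera, 365 missing values of genes were filled with their group mean. Each list is named in the report with its result.

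Groups, contrasts, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the called genes with a symbol that had the largest rises and falls (10 each for the dose means, 5 each for single groups), the 5 smallest adjusted p in each direction for comparisons of doses or compounds (3 smallest p where none passed), up to 4 members of each list in the mean of the compounds at 50 nM, and 10 genes whatever they showed: nr3c1, fkbp5, tsc22d3, per1a, klf9, pck1, pomca, hsd11b2, mmp9 and il1b. Genes outside it, which include unmarked list members and fkbp5 between compounds, were chosen after their values were seen. A gene not well above background on any array of a group is given as a bound. It sets the bright group's mean against the dim arrays' mean of the higher of the probe's signal and the lowest well above background.

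Each result was refitted with normexp background correction (offset 50), quantile normalization, the authors' table, no filter on dim probes, probes well above background on all arrays, the mean of all probes of a gene, the replicate number as a block, the slide as a block, the compared groups alone, array weights, and each array left out in turn. Normexp took each spot's median foreground and background signal, controls included, since the files hold no mean signal. Added after the data were seen were the scan day as a block, the fits without the noisiest array or without the 2 dimmest 5 nM triamcinolone arrays, and the first principal component as a covariate. The steps were tested on data simulated with each gene's mean and residual spread and normal noise, with changes added to some genes. Over the 6 groups against control, a log2 change of 1 was found for 65.7% to 79.1% of genes and one of 0.5 for 10.4% to 32.8% (4 to 12 false calls), and with the slide block for 56.7% and 16.4% (50 nM dexamethasone). With larger changes, 92 of 100 common to 3 compounds and 90 of 100 interactions (6 false calls) were found, and 2 of 2 list tests. Groups that share controls were compared with 100 simulations of unchanged groups that share 4 simulated controls. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.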

Results

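RNA was measured in pools of whole zebrafish larvae at 5 days of age after exposure to a synthetic glucocorticoid from 3 hours of age. Control larvae (DMSO) gave 4 arrays, and dexamethasone, prednisolone and triamcinolone at 5 and 50 nM gave 5 arrays each, so that 7 groups share 34 arrays. The 75th percentile of the intensity was 614.3 to 679.8 on control arrays and 460.1 to 1401.5 over all arrays. Between 80.3% and 90.9% of probes were well above background on every array except 5 nM triamcinolone replicate 1, which had 61.6% and a negative-control standard deviation of 12.36 against at most 4.62 elsewhere. Replicate arrays of a group correlated at a median r of 0.984 across probes (66 pairs, 0.960 to 0.996, probes not independent), and no pair was identical. The study asks which genes the 3 glucocorticoids change in common at doses found in the environment.

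Slides and scan days were not balanced over the groups. The 9 slides were scanned on 5 days: controls 1 and 2 shared slides 1 and 2 with 50 nM replicates, controls 3 and 4 shared slides 3 and 4 with 5 nM replicates, and later slides held no control. The first principal component took 37.3% of the variance (11% of it between groups, 17.7% between slides), the second 11% (89.6% between slides) and the third 7% (61.6% between compounds). Changes below are therefore followed by the value with the slide as a block and the value within the scan day that holds both groups, day 1 for 50 nM and day 2 for 5 nM unless stated. Within such a day a group against control has 4 arrays, limma called at most 2 genes, and all 67, 57 and 222 genes called for dexamethasone, prednisolone and triamcinolone at 50 nM kept their sign, as did 142 of 142, 35 of 35 and 264 of 265 at 5 nM. These arrays are also part of the full fit.

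The mean of the 3 compounds at 50 nM against control can rest on 1 or 2 of them. nr1d1, the clock repressor also known as Rev-erb alpha, fell by 0.95 ± 0.13 log2 (adjusted p = 0.000179, -0.98 with the slide block, -0.97 within the scan day), with 10 of 15 treated arrays below the control mean: it averaged 3.30 with dexamethasone, 1.93 with prednisolone and 0.71 with triamcinolone, against 2.93 in controls. cry5, of the photolyase and cryptochrome family, rose by 0.76 ± 0.10 (adjusted p = 0.000124, 0.72 and 0.84) on 12 of 15 arrays, not with triamcinolone (-2.48, controls -2.44). The immediate early gene fosab fell by 0.78 ± 0.14 (adjusted p = 0.00808, -1.03 and -0.80) and the stress gene gadd45ba by 0.73 ± 0.13 (adjusted p = 0.00854, -0.88 and -0.76), each on 15 of 15 arrays. gch2, a GTP cyclohydrolase of pteridine pigment synthesis, fell by 0.76 ± 0.15 (adjusted p = 0.0182, -0.99 and 1.00 lower) on 13 of 15 arrays, with dexamethasone at 2.28 near the control mean of 2.33. The calls of hmox1b, a heme oxygenase (1.12 ± 0.21), bhlhe41, a clock repressor (-0.84 ± 0.15), and lonrf1 (0.55 ± 0.10) were lost with the slide block, at 1.17, -0.92 and 0.51. These moved on 10, 13 and 9 of 15 arrays, with hmox1b (-0.81, controls -0.59) and bhlhe41 (-0.76, controls -0.84) near control in dexamethasone and lonrf1 raised only there (-0.91 and -1.19 in the others, controls -1.03). In total 26 genes rose and 59 fell (3205 genes at an unadjusted p under 0.05, 1215 expected by chance), and with the slide block 22 were called, 17 of them in both fits.

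The 50 nM mean rests on few control arrays and on the scaling. Its count of 85 became 148, 42, 27 and 12 without controls 1, 2, 3 and 4. Without control 3 the fosab and gadd45ba calls were lost (adjusted p = 0.0636 each) and hmox1b reached 0.0671. Without control 4 bhlhe41 reached 0.0693, lonrf1 0.0951, hmox1b 0.0951 and gch2 0.0802, and gch2 reached 0.101 without control 2. With normexp correction 6 genes were called (3 higher, 3 lower) and nr1d1 alone of these genes kept its call. Quantile normalization called 54 higher and 34 lower, and the cry5 call was also lost with the authors' table and with the mean of its probes, which move apart (0.02 to 0.76).

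At 5 nM the mean of the 3 compounds lowered serpinh1b, the collagen chaperone Hsp47, by 0.87 ± 0.12 log2 (adjusted p = 0.000305, -1.01 with the slide block, -1.03 within the scan day), below every control array on 15 of 15 treated arrays. fosab fell by 0.93 ± 0.14 (adjusted p = 0.000737, -0.83 and -1.06) on 15 of 15 arrays, and gadd45ba by 0.85 ± 0.13 (adjusted p = 0.00144, -0.55 and -0.68) on 15 of 15. nr1d1 fell by 0.84 ± 0.13 (adjusted p = 0.000979, -0.98 and 1.00 lower) on 10 of 15 arrays (3.39 with dexamethasone, controls 2.93). cry5 rose by 0.85 ± 0.10 (adjusted p = 1.87e-05, 0.78 and 0.66) on 12 of 15 arrays (-2.56 with triamcinolone, controls -2.44), rorcb, an orphan nuclear receptor gene, by 1.09 ± 0.16 (adjusted p = 0.000655, 0.93 and 1.14) on 14 of 15, and the light-responsive clock gene per2 by 0.92 ± 0.16 (adjusted p = 0.00587, 1.26 and 1.18) on 12 of 15. In all, 27 genes rose and 26 fell (2386 at an unadjusted p under 0.05). The slide block called 117 (31 higher, 86 lower), 35 of them in both fits.

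Of the named 5 nM genes only fosab and serpinh1b kept their calls under each alternative and each left-out array. The authors' table ended those of cry5, rorcb, nr1d1 and gadd45ba, normexp those of cry5, rorcb and per2, and leaving out control 4 that of per2 (adjusted p = 0.0786). The count of 53 became 31 without control 1, 29 without control 3 and 80 without 5 nM triamcinolone replicate 1. The split was 10 higher and 6 lower with normexp, 65 and 35 with quantile normalization, and 22 and 54 with the authors' table.

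**Figure D1:**
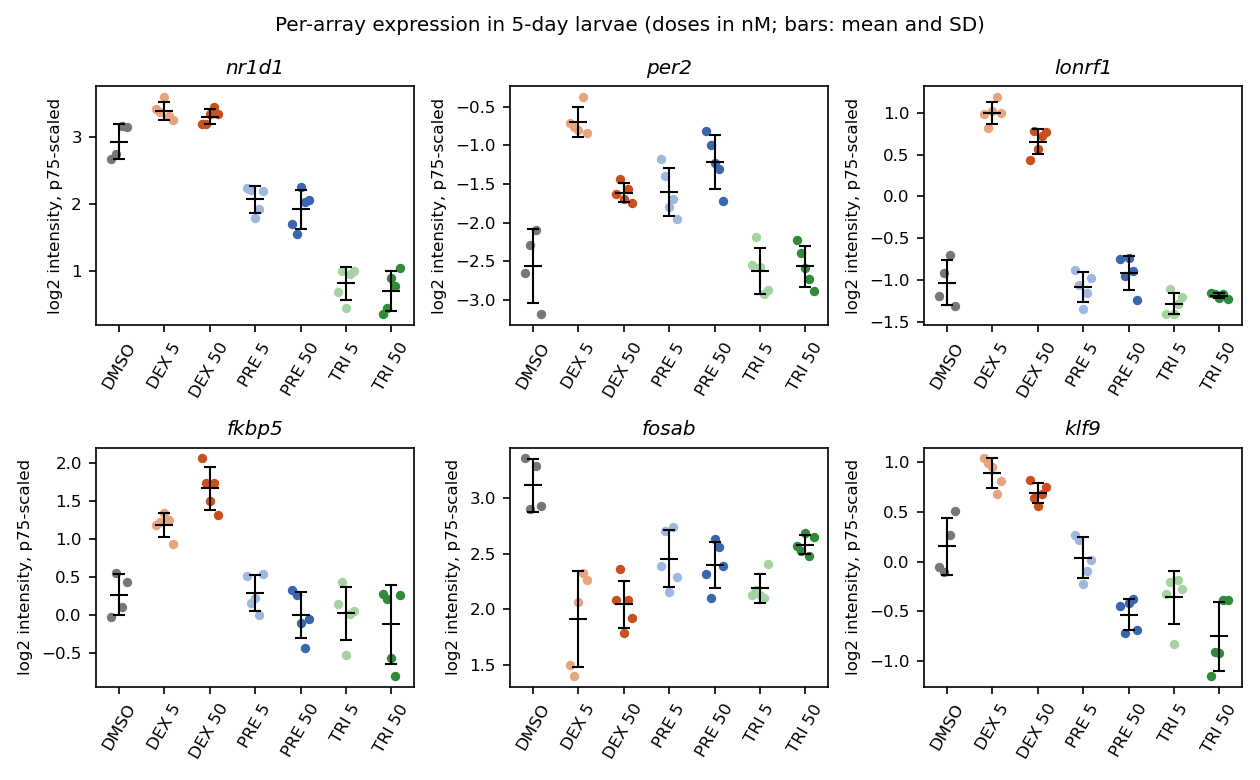
Log2 intensity relative to the array's 75th percentile (vertical axis) of 6 genes on each of the 34 arrays, by group, with bars for the mean and standard deviation. For nr1d1 the 5 arrays of 50 nM triamcinolone average 0.71 and those of 50 nM dexamethasone 3.30, on either side of the control mean of 2.93.

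Dexamethasone at 50 nM, a fluorinated prednisolone with an added methyl group, raised lonrf1, which encodes a RING finger protein, from -1.03 ± 0.27 (SD, n = 4) in controls to 0.66 ± 0.15 (n = 5). That is a log2 change of 1.69 ± 0.12 (adjusted p = 1.42e-10, 1.65 with the slide block, 1.66 within the scan day). fkbp5, a co-chaperone and target of the glucocorticoid receptor, rose by 1.40 ± 0.21 (adjusted p = 0.000525, 1.55 and 1.63), although its other detected probe read -0.38 and the mean of its probes did not pass. cry5 rose by 1.06 ± 0.12 (adjusted p = 2.8e-06, 1.02 and 0.97). gadd45ba changed by -1.20 ± 0.16 (adjusted p = 8.42e-05, -1.35 and -1.20) and fosab by -1.07 ± 0.17 (adjusted p = 0.000667, -1.33 and -0.91). Each of these genes moved on 5 of 5 arrays. Of the 67 called genes 44 rose and 23 fell (2783 at an unadjusted p under 0.05), with 42 called under the slide block and 32 in both fits. The count was 41 without control 4 and 31 without dexamethasone replicate 4. Quantile normalization called 65 higher and 20 lower and 17 and 17 with the authors' table, which lost cry5 and gadd45ba. Normexp lost cry5, and fitting only the compared groups lost fosab.

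Prednisolone at 50 nM raised hmox1b by 1.67 ± 0.25 log2 (adjusted p = 0.000671, 1.72 with the slide block, 1.72 within the scan day), cry5 by 1.27 ± 0.12 (adjusted p = 1.17e-07, 1.23 and 1.40) and per2 by 1.34 ± 0.20 (adjusted p = 0.000555, 1.39 and 1.57). Other probes of cry5 and per2 read -0.31 and -0.59. nr1d1 fell by 1.01 ± 0.15 (adjusted p = 0.000831, -1.04 and -1.08), bhlhe41 by 1.02 ± 0.18 (adjusted p = 0.00608, -1.10 and -1.21), gch2 by 1.01 ± 0.18 (adjusted p = 0.00653, -1.24 and -1.21) and the myc homologue mych by 0.70 ± 0.13 (adjusted p = 0.00653, -0.84 and -0.74). All of these moved on 5 of 5 arrays, and only hmox1b kept its call in each alternative: fitting the 2 groups alone lost per2, nr1d1, bhlhe41, gch2 and mych, normexp lost per2 and gch2, and the mean of probes lost per2 and cry5, the latter also with the authors' table. Prednisolone changed 57 genes (26 higher, 31 lower, 2460 at an unadjusted p under 0.05), 34 with the slide block and 23 in both. The count fell to 22 without control 3 and 19 without control 4, and was 26, 31, 26, 34 and 35 without prednisolone replicates 1 to 5. The split was 11 higher and 4 lower with normexp, 53 and 35 with quantile normalization, and 73 and 137 with the authors' table.

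Triamcinolone at 50 nM, a fluorinated prednisolone with an added hydroxyl group, lowered nr1d1 by 2.22 ± 0.15 log2 (adjusted p = 9.1e-11, -2.25 with the slide block, -2.31 within the scan day). bhlhe41 fell by 1.57 ± 0.18 (adjusted p = 3.16e-06, -1.65 and -2.02) and dbpb, a clock-output transcription factor, by 1.65 ± 0.24 (adjusted p = 0.000146, -1.64 and -1.80). hmox1b rose by 1.91 ± 0.25 (adjusted p = 2.32e-05, 1.96 and 1.67), and fbxo32, the muscle atrophy ubiquitin ligase atrogin, by 1.78 ± 0.32 (adjusted p = 0.00187, 1.72 and 1.70). rorcb rose by 1.46 ± 0.19 (adjusted p = 1.88e-05, 1.44 and 1.05), a call lost with normexp. All 6 moved on 5 of 5 arrays. Of 222 called genes 91 rose and 131 fell (2895 at an unadjusted p under 0.05), with 135 under the slide block and 103 in both, 117 without control 3 and 117 without control 4. Quantile normalization called 127 higher and 106 lower.

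At 5 nM dexamethasone raised lonrf1 by 2.03 ± 0.12 log2 (adjusted p = 9.51e-13, 2.02 with the slide block, 1.90 within the scan day), per2 by 1.86 ± 0.20 (adjusted p = 4.78e-07, 2.03 and 1.91), cry5 by 1.58 ± 0.12 (adjusted p = 2.99e-10, 1.56 and 1.39) and nfil3-6, of a bZIP family with clock roles, by 1.44 ± 0.19 (adjusted p = 2.77e-05, 1.46 within the scan day). klf2a, a flow-responsive endothelial transcription factor, changed by -1.50 ± 0.15 (adjusted p = 1.84e-07, -1.54 and -1.68) and gadd45ba by -1.39 ± 0.16 (adjusted p = 2.72e-06, -1.38 and -1.56). fosab fell by 1.21 ± 0.17 (adjusted p = 4.56e-05, -1.32 and -1.67) and socs3a, a suppressor of cytokine signalling, by 1.17 ± 0.22 (adjusted p = 0.00518, -1.36 and -1.84), both lost when the 2 groups were fitted alone. The trace amine receptor gene taar14b was not well above background on any of these 5 arrays and was at least 1.44-fold lower than in controls (adjusted p = 0.00234, lost with normexp and with the 2 groups alone). Each gene moved on 5 of 5 arrays. Of 142 genes 96 rose and 46 fell (1981 at an unadjusted p under 0.05), with 141 under the slide block and 95 in both. Without control 3 the count was 76 and without dexamethasone replicate 3 it was 93. Normexp called 52 higher and 12 lower.

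At 5 nM prednisolone raised cry3b, a cryptochrome, by 2.00 ± 0.34 log2 (adjusted p = 0.00464, 2.42 with the slide block, 2.25 within the scan day, well above background on 2 of 4 control arrays, so its size is uncertain), rorcb by 1.35 ± 0.19 (adjusted p = 0.000426, 1.16 and 1.28) and cry5 by 1.09 ± 0.12 (adjusted p = 3.79e-06, 1.00 and 0.94). serpinh1b fell by 0.90 ± 0.14 (adjusted p = 0.00181, -1.14 and -1.20). hmox1b rose by 1.46 ± 0.25 (adjusted p = 0.00464, 1.55 and 1.92), a call lost with the slide block and with array weights. These 5 genes moved on 5 of 5 arrays, and each call was lost when the 2 groups were fitted alone, those of cry3b, rorcb and cry5 with normexp, and those of rorcb, cry5 and serpinh1b with the authors' table. The count of 35 (21 higher, 14 lower, 2094 at an unadjusted p under 0.05) was 60 with the slide block, 21 of them in both. It was 23, 23 and 20 without controls 1, 3 and 4, and 53 and 21 without prednisolone replicates 1 and 4. The authors' table called 5 higher and 6 lower.

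At 5 nM triamcinolone lowered nr1d1 by 2.11 ± 0.15 log2 (adjusted p = 1.99e-10, -2.24 with the slide block, -2.31 within the scan day), bhlhe41 by 1.56 ± 0.18 (adjusted p = 2.7e-06, -1.43 and -1.42) and dbpb by 1.54 ± 0.24 (adjusted p = 0.000453, -1.40 and -1.16). mat2ab, of S-adenosylmethionine synthesis, fell by 1.25 ± 0.23 (adjusted p = 0.00271, -1.21 and -1.46). hmox1b rose by 1.85 ± 0.25 (adjusted p = 3.89e-05, 1.94 and 1.87), rorcb by 1.65 ± 0.19 (adjusted p = 2.11e-06, 1.46 and 1.65) and fbxo32 by 1.61 ± 0.32 (adjusted p = 0.00625, 2.15 and 1.86). Each moved on 5 of 5 arrays. Normexp ended the calls of dbpb, mat2ab and rorcb, and the fit of the 2 groups alone those of dbpb, mat2ab and fbxo32. The 265 called genes, 98 higher and 167 lower (2999 at an unadjusted p under 0.05), compare with 365 under the slide block, 140 of them in both fits. The count was 174 and 163 without controls 2 and 3 and 169 without triamcinolone replicate 3. The split was 18 higher and 20 lower with normexp, 123 and 116 with quantile normalization, and 129 and 400 with the authors' table.

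Some genes recurred across groups with weaker evidence. dmrt1, a transcription factor of gonadal sex determination, rose by 1.70 ± 0.29 log2 with 50 nM dexamethasone (adjusted p = 0.00344, 1.42 with the slide block, 1.28 within the scan day), by 1.81 ± 0.29 with 50 nM triamcinolone (adjusted p = 0.000553, 1.53 with the slide block) and by 1.94 ± 0.29 with 5 nM dexamethasone (adjusted p = 0.000215, 1.73 and 2.14), on 5 of 5 arrays each. Its other detected probes read as low as 0.14, -0.26 and 0.43. Normexp ended all 3 calls, the mean of probes those at 50 nM, and the authors' table and the 2 groups alone that of 50 nM dexamethasone. cry3b rose by 1.86 ± 0.34 with 5 nM triamcinolone (adjusted p = 0.00319, 2.27 and 2.37) and by 1.59 ± 0.34 at 50 nM (adjusted p = 0.0124, 1.86 and 1.80), of uncertain size as at 5 nM prednisolone. The 50 nM call was lost without control 1 (0.0664), and both with normexp and with the 2 groups alone. With 5 nM prednisolone nr1d1 fell by 0.86 ± 0.15 (adjusted p = 0.00686, -0.98 and -0.92), lost without control 3 or 4 (0.0554 each), with the authors' table and with the 2 groups alone.

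**Figure D2:**
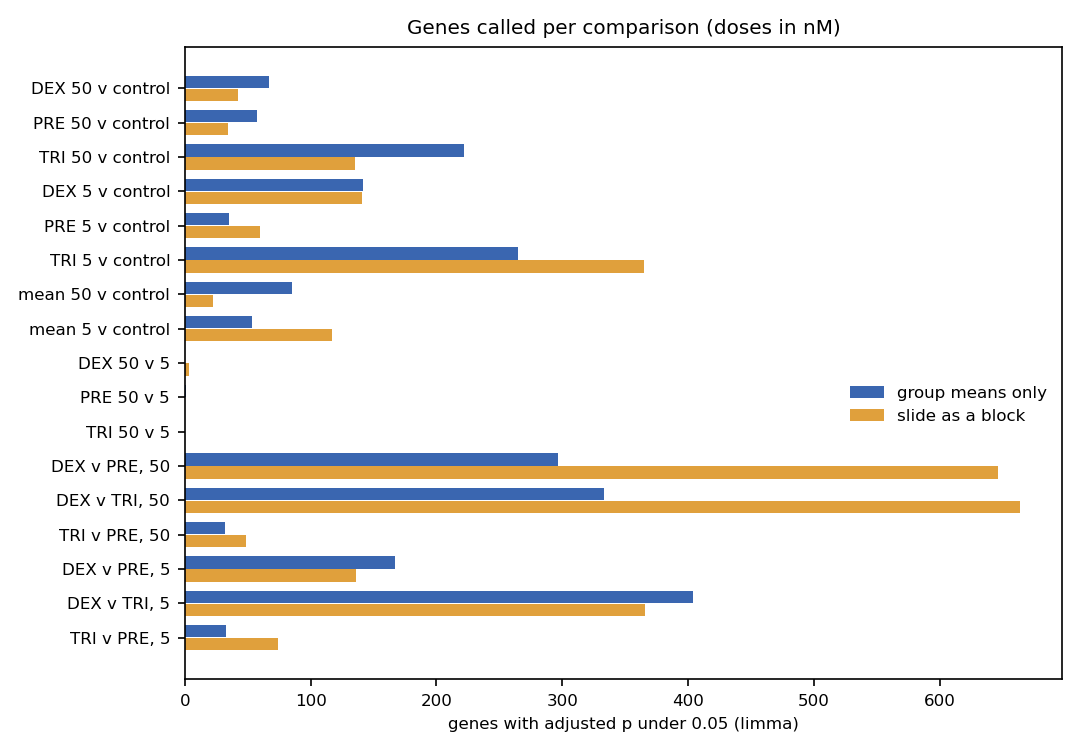
Number of genes with an adjusted p under 0.05 by limma (horizontal axis) for each comparison, with group means only and with the slide as a block. The largest count with group means only is 404, for dexamethasone against triamcinolone at 5 nM, and the comparisons of doses within a compound have 0 or 1.

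Between 50 and 5 nM of the same compound limma called few genes. No gene passed for dexamethasone or triamcinolone (1326 and 1461 genes at an unadjusted p under 0.05), where klf2a came closest with 0.76 ± 0.14 log2 higher at 50 nM of dexamethasone (adjusted p = 0.089) and 0.77 ± 0.14 lower at 50 nM of triamcinolone (-0.77, adjusted p = 0.113). per2 read 0.92 ± 0.19 lower at 50 nM of dexamethasone (-0.92, adjusted p = 0.129), -1.03 with the slide block, where it passed, and -1.05 within scan day 3. esm1, an endothelial proteoglycan gene, read 0.78 ± 0.15 higher at 50 nM of triamcinolone (adjusted p = 0.113). zpax4 was not well above background on any 50 nM triamcinolone array, at least 1.81-fold lower (adjusted p = 0.247). For prednisolone 1 gene passed, zgc:193593, chosen after its values were seen, 0.73 log2 higher at 50 nM (adjusted p = 0.00925), while ssrp1a, a histone chaperone subunit, read 0.61 ± 0.12 (adjusted p = 0.114).

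The 95% intervals of these dose differences reached a median of 0.36 log2 to either side, and 89.9%, 88.9% and 89.8% of the genes had an interval inside a log2 change of 1 either way for dexamethasone, prednisolone and triamcinolone. With the slide block 3, 0 and 0 genes were called. Prednisolone had 2230 genes at an unadjusted p under 0.05. Its count was 0 without 50 nM replicate 3 or 4 or 5 nM replicate 2 or 3, 4 without 5 nM replicate 1 and 28 without 5 nM replicate 5. The dexamethasone count was 3 without 5 nM replicate 3, and that of triamcinolone 1 and 2 without 5 nM replicates 1 and 5. No slide held both doses of prednisolone or of triamcinolone. Genes called at both doses moved the same way: 46 for dexamethasone, 21 for prednisolone and 133 for triamcinolone, with 0 opposite, against 0.217, 0.0403 and 1.27 for independent lists. The doses share their controls: with each dose set against its own pair of them (6 splits) 12 to 21, 3 to 5 and 30 to 34 calls were shared, 0 opposite, and the covariance of fold changes averaged 0.0142 (-0.0108 to 0.0364), 0.0055 (-0.0113 to 0.0286) and 0.0216 (-0.0215 to 0.0384). With all controls it was 0.0501, 0.0413 and 0.0574, against 0.0381, 0.0334 and 0.0366 in simulated unchanged groups, which shared a median of 0 calls (highest 1142, 2242 and 3901).

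Interaction of compound and dose was called by limma for klf2a alone (F = 31.3, adjusted p = 0.00108). Its change from 5 to 50 nM was 0.76 for dexamethasone, -0.33 for prednisolone and -0.77 for triamcinolone. Its level was 2.94 ± 0.24 in controls (SD, n = 4), 1.45 ± 0.19 at 5 nM and 2.21 ± 0.24 at 50 nM of dexamethasone, and 2.61 ± 0.28 at 5 nM and 1.84 ± 0.13 at 50 nM of triamcinolone (n = 5 each). At an unadjusted p under 0.05 there were 481 genes. With the slide block, with normexp or with the mean of probes 0 genes were called, and 2 without 5 nM dexamethasone replicate 3 or 5 nM triamcinolone replicate 2.

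No gene was called in the same direction for all 3 compounds at 50 nM, out of 287 called for any and 55 for at least 2. At 5 nM 3 genes were: serpinh1b fell by 1.15, 0.90 and 0.55 log2 with dexamethasone, prednisolone and triamcinolone, ENSDART00000125347 rose by 1.40, 2.89 and 2.93, and EH584150 fell by 0.61, 0.89 and 0.77, the last 2 chosen after their values were seen. These were among 373 genes called for any compound and 54 for at least 2. Simulated unchanged groups with shared simulated controls had a median of 0 genes in common at either dose (highest 826 at 50 nM and 5516 at 5 nM), and independent lists would share 0.000334 and 0.000517. With the slide block the counts were 0 and 4. Without control 1 the 50 nM count was 3, without control 2 it was 2, and it was 1 without dexamethasone replicate 1 or prednisolone replicate 4. The 5 nM count was 1 without control 2, 3 or 4 or triamcinolone replicate 4, and 1 (higher) with normexp.

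Pairs of compounds shared more calls than all 3. At 50 nM prednisolone and triamcinolone shared 33 genes in direction and 0 opposite, dexamethasone and triamcinolone 18 and 4, and dexamethasone and prednisolone 4 and 1, against 0.264, 0.289 and 0.0764 for independent lists. Fold changes correlated across genes at 0.81, 0.53 and 0.60, where simulated unchanged groups gave 0.57 for each pair. Covariances were 0.0656, 0.0468 and 0.0486 against simulated 0.0347, 0.0368 and 0.035, so differences of 0.0309, 0.00999 and 0.0136. With each compound set against its own pair of controls (6 splits) the covariance averaged 0.0298 (0.0114 to 0.044), 0.011 (-0.025 to 0.0301) and 0.0127 (-0.0196 to 0.028), r 0.27, 0.11 and 0.13, and 2 to 9, 3 to 5 and 2 to 3 calls were shared.

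The same pairs at 5 nM shared 29 genes with 0 opposite, 23 with 12 opposite and 8 with 0 opposite (independent lists 0.181, 0.703 and 0.109). Correlations across genes were 0.44, 0.44 and 0.63 against simulated 0.59, 0.56 and 0.61. Covariances were 0.0344, 0.0353 and 0.0451 against simulated 0.0354, 0.0369 and 0.0346, so differences of -0.000958, -0.00169 and 0.0105. With split controls they averaged -0.00143 (-0.0389 to 0.0151), -0.000577 (-0.0328 to 0.0134) and 0.00927 (-0.0109 to 0.0232), r 0.01, 0.01 and 0.10, and 1 to 12, 4 to 7 and 3 to 7 calls were shared.

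Compounds were compared at matched dose without the control arrays. At 50 nM they lie on the same slides, so the slide block leaves each difference as it is. Dexamethasone against triamcinolone, which carry a methyl or a hydroxyl group at the same carbon, gave 333 genes at 50 nM (220 higher, 113 lower with dexamethasone, 2217 at an unadjusted p under 0.05). nr1d1 was 2.59 ± 0.14 log2 higher with dexamethasone (adjusted p = 1.14e-13, 2.59 with the slide block, 2.79 within scan day 1), lonrf1 1.84 ± 0.11 (adjusted p = 6.58e-13, 1.84 and 1.77) and cry2 1.82 ± 0.15 (adjusted p = 6.93e-10, 1.82 and 2.06). The period gene per1b was 1.25 ± 0.11 higher (adjusted p = 4.97e-09, 1.25 and 1.32). hmox1b was lower with dexamethasone, at -2.14 ± 0.24 (adjusted p = 3.6e-07, -2.14 and -2.15), as were rorcb at -1.57 ± 0.18 (adjusted p = 5.33e-07, -1.57 and -1.32) and ndrg1b at -1.03 ± 0.11 (adjusted p = 4.3e-07, -1.03 and 1.00 lower). Each separated 5 of 5 arrays, and these calls held in every alternative and with each array left out. The slide block called 664 genes, 333 of them in both, and 603 were higher and 580 lower in the authors' values.

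At 5 nM dexamethasone against triamcinolone gave 404 genes, 303 higher and 101 lower with dexamethasone (2674 at an unadjusted p under 0.05, 366 with the slide block, 233 in both). nr1d1 was 2.57 ± 0.14 log2 higher (adjusted p = 1.39e-13, 2.50 with the slide block, 2.55 within scan day 2), lonrf1 2.28 ± 0.11 (adjusted p = 3.54e-15, 2.17 and 2.16), cry5 1.71 ± 0.11 (adjusted p = 4.55e-12, 1.78 and 1.72) and the cell death gene bokb 1.60 ± 0.11 (adjusted p = 2.45e-11, 1.58 and 1.65). hmox1b was lower at -1.90 ± 0.24 (adjusted p = 2.55e-06, -1.87 and -1.49), rorcb at -1.39 ± 0.18 (adjusted p = 4.04e-06, -1.30 and -1.18) and ndrg1b at -1.12 ± 0.11 (adjusted p = 7.93e-08, -1.27 and -1.35). All separated 5 of 5 arrays and kept their calls in every alternative and with each array left out. Of the 333 genes called at 50 nM and 404 at 5 nM, 188 were the same genes in the same direction and 0 opposite, against 3.21 for independent lists.

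**Figure D3:**
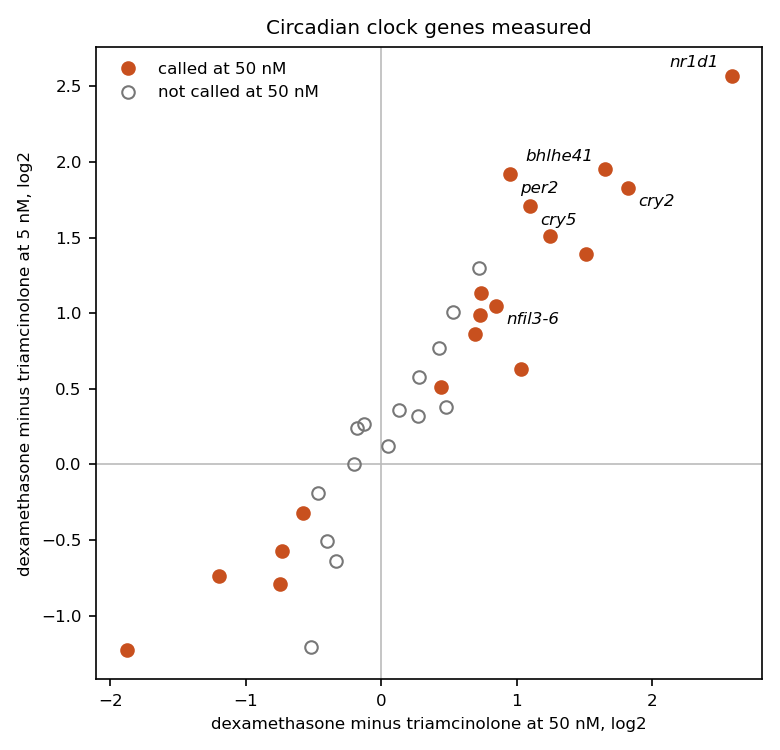
Log2 difference of dexamethasone minus triamcinolone at 50 nM (horizontal axis) and at 5 nM (vertical axis) for the 33 measured genes of the circadian clock list. Of these, 30 have the same sign at both doses, and nr1d1 lies farthest out at 2.59 and 2.57.

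Dexamethasone against prednisolone, which lacks the fluorine and the methyl group, gave 297 genes at 50 nM (172 higher, 125 lower with dexamethasone, 2273 at an unadjusted p under 0.05). lonrf1 was 1.57 ± 0.11 log2 higher (adjusted p = 6.52e-11, 1.57 with the slide block, 1.46 within scan day 1), nr1d1 1.38 ± 0.14 (adjusted p = 5.6e-07, 1.38 and 1.56), guca1c, a photoreceptor guanylate cyclase activator, 1.51 ± 0.17 (adjusted p = 1.12e-06, 1.51 and 1.69) and bokb 1.05 ± 0.11 (adjusted p = 7.48e-07, 1.05 and 0.95). hmox1b was lower at -1.90 ± 0.24 (adjusted p = 8.18e-06, -1.90 and -2.20), ndrg1b at -1.14 ± 0.11 (adjusted p = 3e-07, -1.14 and -1.22) and gadd45ba at -0.95 ± 0.15 (adjusted p = 0.000355, -0.95 and -0.98). These separated 5 of 5 arrays and held in every alternative. The slide block called 646 genes, 296 of them in both. The count was 189 and 174 without dexamethasone replicates 3 and 4, and 164, 180 and 194 without prednisolone replicates 1, 3 and 4.

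The same pair at 5 nM gave 167 genes (102 higher, 65 lower with dexamethasone, 1859 at an unadjusted p under 0.05), 136 with the slide block and 84 in both. lonrf1 was 2.09 ± 0.11 log2 higher (adjusted p = 8.89e-14, 1.97 with the slide block, 1.87 within scan day 2), cry2 1.29 ± 0.15 (adjusted p = 2.43e-06, 1.24 and 1.38), bokb 1.09 ± 0.11 (adjusted p = 4.29e-07, 1.07 and 1.05) and mpdu1b, of dolichol-linked sugar use, 0.92 ± 0.11 (adjusted p = 1.14e-05, 0.97 and 0.83). klf2a was lower at -1.61 ± 0.14 (adjusted p = 1.21e-08, -1.75 and -1.95) and ndrg1b at -0.94 ± 0.11 (adjusted p = 8.45e-06, -1.10 and -1.14). nr1d1 was 1.32 ± 0.14 higher (adjusted p = 1.37e-06, 1.24 and 1.17), lost with the authors' table, and hmox1b lower at -1.50 ± 0.24 (adjusted p = 0.000335, -1.47 and -1.54), lost with the slide block. All separated 5 of 5 arrays. The count was 110 without dexamethasone replicate 4. Across doses 112 genes were called for this pair in the same direction and 0 opposite, against 1.06 for independent lists.

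Triamcinolone and prednisolone, which differ by a fluorine and a hydroxyl group, gave 32 genes at 50 nM (9 higher, 23 lower with triamcinolone, 723 at an unadjusted p under 0.05) and 33 at 5 nM (5 higher, 28 lower, 2677). At 50 nM cry5 was lower with triamcinolone at -1.31 ± 0.11 log2 (adjusted p = 2.51e-08, -1.31 with the slide block, -1.25 within scan day 1), per2 at -1.35 ± 0.19 (adjusted p = 0.000159, -1.35 and -1.40) and the clock-output gene tefa at -0.75 ± 0.07 (adjusted p = 1.12e-07, -0.75 and -0.78). At 5 nM cry5 was lower at -1.21 ± 0.11 (adjusted p = 1.65e-07, -1.21 and -1.28 within scan day 2) and nr1d1 at -1.26 ± 0.14 (adjusted p = 8.88e-06, -1.26 and -1.39). At 50 nM nr1d1 read -1.21 ± 0.14 (adjusted p = 1.92e-05, -1.21 and -1.23), lost when the 2 groups were fitted alone. All separated 5 of 5 arrays. With the slide block 49 and 74 genes were called, 31 and 32 in both fits, and 19 genes were called at both doses with 0 opposite (0.0283 for independent lists). Without 50 nM triamcinolone replicate 3 the count was 20. The authors' table called 27 higher and 36 lower at 50 nM. At 5 nM normexp called 3 higher and 7 lower and quantile normalization 10 and 25.

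Where the test called no difference, intervals bound it. At 50 nM 91.1%, 90.3% and 93.3% of the 24304 genes had a 95% interval within a log2 change of 1 for dexamethasone against prednisolone, dexamethasone against triamcinolone and triamcinolone against prednisolone. At 5 nM the shares were 91.1%, 87.5% and 86% in the same order. The intervals reached a median of 0.36 to either side.

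Known targets of the glucocorticoid receptor were fixed as a list, of which 24 were measured. Their mean was 1.14 ± 0.10 (SD, n = 4) in controls and 0.91 ± 0.06 (n = 5) with 50 nM triamcinolone, a difference of -0.23 (95% interval -0.36 to -0.09, exact permutation p = 0.0159, adjusted 0.0595, 0 of 5 arrays above the control mean, -0.21 with the slide block and -0.18 within the scan day). It lay 0.05 above control with 50 nM dexamethasone (-0.08 to 0.19, exact p = 0.46) and -0.10 from it with 50 nM prednisolone (-0.24 to 0.03, exact p = 0.0952). At 5 nM the differences were 0.07 (-0.06 to 0.21) for dexamethasone, -0.02 (-0.15 to 0.12) for prednisolone and -0.13 (-0.27 to 0.01) for triamcinolone. Between 50 and 5 nM it differed by -0.02, -0.09 and -0.10 for dexamethasone, prednisolone and triamcinolone.

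Between compounds the receptor target mean was 0.28 higher with dexamethasone than with triamcinolone at 50 nM (0.15 to 0.41, exact p = 0.00794, the smallest that 5 against 5 arrays allow, adjusted 0.0595, 0.28 with the slide block and 0.33 within the scan day, 5 of 5 arrays). It was 0.16 higher than with prednisolone (0.03 to 0.28, exact p = 0.0159, 0.16 with the slide block and 0.15 within the day). Triamcinolone lay -0.12 from prednisolone (-0.25 to 0.01, exact p = 0.0159). At 5 nM dexamethasone lay 0.20 above triamcinolone (0.07 to 0.33, exact p = 0.0556) and 0.09 above prednisolone (-0.04 to 0.22), and triamcinolone -0.11 from prednisolone (-0.24 to 0.01). None of the 15 comparisons passed the adjustment. With the slide as a block (not permuted within slides) 3 did, at 50 nM: triamcinolone against control and dexamethasone against each other compound. Without 5 nM triamcinolone replicate 4 the 5 nM difference of dexamethasone and triamcinolone was 0.25, with an adjusted p of 0.0476.

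Among genes reported whatever they showed, klf9, induced by the receptor in many tissues, rose with 5 nM dexamethasone by 0.74 ± 0.15 log2 (adjusted p = 0.0133, 0.67 with the slide block, 0.63 within the scan day) and fell with 50 nM triamcinolone by 0.91 ± 0.15 (adjusted p = 0.000971, -0.80 and -0.95). The rise was lost without control 1 (adjusted p = 0.0715) or control 2 (0.0853), with normexp, with the authors' table and with the 2 groups alone, which also ended the fall. klf9 read 0.53 ± 0.15 with 50 nM dexamethasone (adjusted p = 0.148, passing with the mean of probes at 0.70, array weights and the scan day as a block), -0.52 with 5 nM triamcinolone (adjusted p = 0.103, passing in 3 of 14 alternatives) and -0.69 ± 0.15 with 50 nM prednisolone. The latter passed (0.0432) and was lost with the slide block (-0.58), the scan day as a block, normexp, no filter on dim probes, array weights and the 2 groups alone, and without control 3 (0.176), control 4 (0.236) or prednisolone replicate 1 (0.0783), 2 (0.109), 3 (0.0763), 4 (0.0681) or 5 (0.0967). tsc22d3, the glucocorticoid-induced leucine zipper, read -0.55 ± 0.13 with 50 nM triamcinolone (adjusted p = 0.0298). That call was lost with the slide block (-0.33), the scan day as a block, normexp, the authors' table, array weights and the 2 groups alone, and without control 3 (0.141), control 4 (0.158) or triamcinolone replicate 2 (0.0577), 3 (0.0884) or 4 (0.0592).

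fkbp5 read 0.91 ± 0.21 with 5 nM dexamethasone (adjusted p = 0.0337, 1.15 with the slide block, 0.93 within the scan day), a call lost without control 1 (0.137), 3 (0.136) or 4 (0.0532), without dexamethasone replicate 1 (0.0528), 2 (0.0745), 3 (0.0993) or 4 (0.0771), with the authors' table and with the mean of its probes. With the other compounds it read -0.27 and -0.39 at 50 nM and 0.02 and -0.25 at 5 nM for prednisolone and triamcinolone (with the mean of probes -0.94 at 50 nM triamcinolone, adjusted p = 0.000553), and it was 1.79 higher with dexamethasone than with triamcinolone at 50 nM (adjusted p = 4.3e-07). The receptor gene nr3c1 read 0.03 ± 0.12 in the 50 nM mean and 0.04 ± 0.12 in the 5 nM mean (95% intervals -0.22 to 0.27 and -0.21 to 0.29). In the 50 nM mean the gluconeogenic pck1 read -0.19 (-0.96 to 0.59), the corticotropin precursor pomca -0.02 (-0.90 to 0.87), the cortisol-inactivating hsd11b2 0.28 (-0.06 to 0.61), the protease mmp9 0.30 (-0.36 to 0.95), the cytokine il1b -0.29 (-1.02 to 0.43) and the period gene per1a -0.34 (-0.85 to 0.17). None of these 7 genes was called by limma in any of the 8 contrasts with control. Alternatives called hsd11b2 with 50 nM dexamethasone (up to 0.81, with array weights) and per1a with triamcinolone at both doses (-1.20 with the mean of probes).

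Lists fixed in advance were tested by camera, and 50 of 216 tests passed with the preset correlation, 0 with an estimated one and 33 with the slide block, 24 of them the same calls. Unless another value is given, the adjusted p of a called list was 0.965 with an estimated correlation. A list's median log2 change is followed by its value with the slide block and within the scan day. After a list's result stand the arrays whose removal ended the call, with the adjusted p reached.

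Circadian clock genes, 33 measured, rose as a group with dexamethasone at 5 nM (median 0.32, 0.26 and 0.40, adjusted p = 1.52e-16, and adjusted p = 0.18 with an estimated correlation). per1b, per2, cry1a, cry2, cry5, tefa, nfil3 and nfil3-6 rose and none fell (12 and 0 adjusted over the list alone). At 50 nM dexamethasone 4 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.08, -0.00 and 0.12, adjusted p = 5.25e-06, and adjusted p = 0.67 with an estimated correlation). With 50 nM triamcinolone the list was lower (median -0.09, -0.09 and -0.30, adjusted p = 0.0163), where nr1d1, bhlhe41, dbpb, per1b, cry2, tefa and hlfa fell and cry3a, cry3b, bmal1a and nfil3-5 rose (6 rose and 10 fell adjusted over the list alone). With 5 nM prednisolone 5 rose and nr1d1 fell (10 and 4 adjusted over the list alone, median 0.15, 0.12 and 0.26, adjusted p = 0.0135), and in the 5 nM mean 5 rose and 1 fell (11 and 3, median 0.06, 0.10 and 0.13, adjusted p = 0.00718). No single array ended these calls. The members named here were called over all genes.

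Receptor targets were lower as a list with 50 nM triamcinolone (median -0.31, -0.21 and -0.30, adjusted p = 0.000439, and adjusted p = 0.21 with an estimated correlation). tsc22d3, per1b, klf9 and socs3a fell and fbxo32 rose (1 rose and 8 fell adjusted over the list alone). Inflammatory mediators, 35 measured, were lower in the same group (median -0.23, -0.38 and -0.28, adjusted p = 0.0163, control 3 0.112, triamcinolone replicate 5 0.0533). The fallen members were the cytokine signalling suppressors socs1a and socs3a (0 rose and 3 fell adjusted over the list alone). Neutrophil and macrophage markers, 28 measured, were higher with 50 nM dexamethasone (median 0.31, 0.29 and 0.53, adjusted p = 6.2e-05) with 0 members called (1 and 0 adjusted over the list alone) and 22 of 28 positive. With 50 nM triamcinolone they were lower (median -0.19, -0.27 and 0.11, adjusted p = 0.0494, 0 called either way, control 3 0.588, triamcinolone replicate 3 0.185 and 5 0.131). Lymphoid markers, 15 measured, passed nowhere (lowest adjusted p = 0.133, 0 called, up to 2 fallen adjusted over the list alone).

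Heat shock and oxidative stress genes, 45 measured, were lower with 5 nM prednisolone (median -0.16, -0.14 and -0.26, adjusted p = 1.29e-05, and adjusted p = 0.193 with an estimated correlation), where the cytosolic chaperone hsp90aa1.1 and serpinh1b fell (0 rose and 5 fell adjusted over the list alone). In the 5 nM mean hsp90aa1.1, serpinh1b, fosab and gadd45ba fell (1 rose and 7 fell adjusted over the list alone, median -0.08, -0.08 and -0.22, adjusted p = 0.00773, and adjusted p = 0.67 with an estimated correlation). With 50 nM prednisolone hsp90aa1.1 fell (0 and 4, median -0.07, -0.11 and -0.09, adjusted p = 0.0117, and adjusted p = 0.702 with an estimated correlation). That call ended without prednisolone replicate 3 (0.141), and its direction turned with normexp.

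Photoreceptor genes, 43 measured, were higher with 5 nM dexamethasone (median 0.09, -0.02 and 0.23, adjusted p = 0.000169), a call lost with the slide block. The cone arrestin arr3b, guca1c, the cone opsin kinase grk7a and rbp4l rose (7 and 0 adjusted over the list alone). With 50 nM dexamethasone guca1c rose (3 and 0 adjusted over the list alone, median 0.03, -0.14 and -0.17, adjusted p = 0.0244, control 3 0.243, dexamethasone replicate 2 0.0547 and 5 0.178), and the direction turned with the slide block and the authors' table. With 50 nM prednisolone 0 were called (1 rose and 3 fell adjusted over the list alone, median 0.21, 0.03 and -0.11, adjusted p = 0.0211, lost with the slide block, control 3 0.178, prednisolone replicate 3 0.18 and 4 0.0915). With triamcinolone, where the list did not pass, 6 members fell and 0 rose at 5 nM and 4 fell and 1 rose at 50 nM (9 and 2, and 8 and 4 adjusted over the list alone). Lens genes, 38 measured, were higher with 50 nM prednisolone (median 0.14, 0.22 and 0.41, adjusted p = 0.00773, control 1 0.207, prednisolone replicate 2 0.0558) and 50 nM triamcinolone (0.13, 0.24 and 0.26, adjusted p = 0.0163, control 1 0.274, triamcinolone replicate 4 0.0639). They were also higher with 5 nM triamcinolone (0.30, 0.09 and 0.14, adjusted p = 0.0011) and in the 5 nM mean (0.16, 0.08 and 0.04, adjusted p = 0.013, control 1 0.354), both lost with the slide block. In these 4 contrasts no lens gene was called, and at most 1 rose adjusted over the list alone. Neuronal markers, 40 measured, were higher with 5 nM prednisolone (median 0.13, 0.06 and 0.21, adjusted p = 0.0493, 0 called either way, lost with the slide block, controls 2 0.0656, 3 0.164 and 4 0.0936, prednisolone replicates 2 0.215, 4 0.259 and 5 0.064).

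Exocrine pancreas genes, 24 measured, were higher with 5 nM triamcinolone (median 0.64, 0.90 and 0.44, adjusted p = 0.000757), with 24 of 24 positive, 0 called and 0 adjusted over the list alone. With 50 nM dexamethasone 22 of 24 were positive (median 0.25, 0.74 and 0.38, adjusted p = 0.0494, 0 called either way, controls 1 0.393, 2 0.148 and 4 0.0771, dexamethasone replicates 1 0.446, 3 0.221 and 4 0.271). The mean of this list ran from -0.04 to 3.63 over the arrays. Intestinal genes, 27 measured, were lower with 50 nM triamcinolone (median -0.44, -0.12 and 0.39, adjusted p = 0.00718, control 3 0.0506, triamcinolone replicates 3 0.0957 and 5 0.281) and 5 nM prednisolone (-0.30, -0.29 and -0.58, adjusted p = 0.00773, control 3 0.0732, prednisolone replicates 2 0.167 and 4 0.0887). Liver genes, 27 measured, were higher with 5 nM triamcinolone (0.22, 0.21 and -0.01, adjusted p = 0.0338, controls 1 0.229 and 2 0.0981, triamcinolone replicates 1 0.134, 3 0.091 and 4 0.0912). The intestinal and liver calls were lost with the slide block, and in each 0 members were called, also adjusted over the list alone.

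Sterol synthesis genes, 26 measured, were lower with 50 nM prednisolone (median -0.16, -0.17 and -0.23, adjusted p = 0.00342, and adjusted p = 0.904 with an estimated correlation), with 0 called and 3 fallen adjusted over the list alone, and with 5 nM prednisolone (-0.11, -0.24 and -0.22, adjusted p = 0.0163, 0 called either way, control 4 0.0562, prednisolone replicate 1 0.0703). Glycolysis genes, 31 measured, were higher in 6 contrasts with small medians: 0.10 with 50 nM prednisolone (adjusted p = 0.0163, control 3 0.092), 0.07 with 5 nM triamcinolone (adjusted p = 0.0163, control 3 0.129, triamcinolone replicate 3 0.0719), 0.08 in the 5 nM mean (adjusted p = 0.0163, control 3 0.127) and 0.07 in the 50 nM mean (adjusted p = 0.0306, control 3 0.164). With 50 nM triamcinolone the median was 0.06 (adjusted p = 0.0494, controls 2 0.056 and 3 0.179, triamcinolone replicates 1 0.0622, 2 0.0771, 3 0.08 and 4 0.0973) and with 5 nM dexamethasone 0.11 (adjusted p = 0.0493, controls 2 0.0514, 3 0.215 and 4 0.0663, dexamethasone replicates 2 0.0504, 3 0.109 and 4 0.0666). All 6 were lost with the slide block, where medians were -0.02 to 0.03, and within the scan day they were -0.09 to 0.12. pfkfb3 alone was called, in the 50 nM mean, a call lost with the slide block and when any 1 of 15 of the 19 arrays was left out, and at most 1 member rose adjusted over the list alone. Gluconeogenesis genes, 31 measured, were higher with 5 nM triamcinolone (median 0.04, 0.04 and -0.04, adjusted p = 0.0493, lost with the slide block, controls 1 0.104, 2 0.057 and 4 0.0734, triamcinolone replicates 1 0.0691, 2 0.0607, 3 0.0926 and 4 0.137), and the arginase gene arg2 rose (1 rose and 1 fell adjusted over the list alone).

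Muscle protein breakdown genes, 27 measured, were higher with 5 nM triamcinolone (median 0.08, 0.02 and 0.03, adjusted p = 0.0338, and adjusted p = 0.241 with an estimated correlation), where fbxo32 rose and the calpain capn3b fell (2 and 1 adjusted over the list alone, control 1 0.0835, triamcinolone replicate 2 0.0518). In the 5 nM mean the median was 0.05 (0.02 and 0.06, adjusted p = 0.0494, and adjusted p = 0.384 with an estimated correlation, 0 called, 2 rose and 1 fell adjusted over the list alone). That call ended without control 1 (0.209), 2 (0.054) or 4 (0.0631), dexamethasone replicate 2 (0.0585), 3 (0.0524) or 4 (0.0582), prednisolone replicate 1 (0.0838), or triamcinolone replicate 1 (0.0593), 2 (0.0614), 3 (0.0514) or 4 (0.0554). Both were lost with the slide block. Muscle structural genes, 49 measured, passed nowhere (lowest adjusted p = 0.332, 0 called). Cartilage and bone matrix genes, 45 measured, were lower with 50 nM prednisolone (median -0.13, -0.07 and 0.07, adjusted p = 0.0384, controls 3 0.0905 and 4 0.159, prednisolone replicates 3 0.755 and 4 0.0504), 50 nM triamcinolone (-0.13, -0.07 and 0.09, adjusted p = 0.0393, controls 3 0.0883 and 4 0.159, triamcinolone replicates 3 0.215 and 5 0.56) and 5 nM prednisolone (-0.08, -0.14 and -0.24, adjusted p = 0.00718, control 4 0.0771, prednisolone replicates 2 0.119 and 4 0.0531). The 50 nM calls were lost with the slide block and turned direction with normexp, and in these 3 contrasts no member was called, with at most 2 fallen adjusted over the list alone.

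Cell cycle genes, 57 measured, were lower with 5 nM prednisolone (median -0.05, -0.16 and -0.12, adjusted p = 0.00162, 0 called and 5 fallen adjusted over the list alone, prednisolone replicate 1 0.0838) and 5 nM dexamethasone (-0.04, -0.09 and -0.04, adjusted p = 0.0355, controls 1 0.248 and 4 0.114, dexamethasone replicates 1 0.155, 3 0.0914 and 4 0.0582). They were higher with 50 nM triamcinolone (0.10, 0.04 and 0.01, adjusted p = 0.00773, 3 rose adjusted over the list alone, control 2 0.0527) and 50 nM dexamethasone (0.05, -0.01 and -0.00, adjusted p = 0.0494, lost with the slide block, controls 2 0.193 and 3 0.19, dexamethasone replicates 1 0.0873, 3 0.134 and 5 0.0876). The direction turned with normexp at 5 nM dexamethasone and with the mean of probes at 50 nM. Xenobiotic metabolism genes, 54 measured, were higher with 50 nM dexamethasone (median 0.10, 0.25 and 0.09, adjusted p = 0.00718, 0 called, 2 rose adjusted over the list alone, control 1 0.0784, dexamethasone replicates 1 0.077, 3 0.0836 and 4 0.054). They were lower with 5 nM prednisolone (-0.17, -0.14 and -0.30, adjusted p = 0.0393, controls 3 0.452 and 4 0.0561, prednisolone replicates 2 0.54 and 4 0.381). With 5 nM triamcinolone they were higher (0.10, 0.07 and -0.04, adjusted p = 0.0474, controls 1 0.246, 2 0.106 and 4 0.0871, triamcinolone replicates 1 0.132, 3 0.203 and 4 0.147) while the aldehyde oxidase aox5 fell (0 rose and 1 fell adjusted over the list alone), and the 5 nM calls were lost with the slide block.

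Ionocyte genes, 42 measured, were lower with 5 nM prednisolone (median -0.11, -0.10 and -0.16, adjusted p = 0.00978, and adjusted p = 0.443 with an estimated correlation) and 50 nM triamcinolone (-0.20, -0.09 and -0.03, adjusted p = 0.0429, and adjusted p = 0.705 with an estimated correlation, controls 2 0.0522 and 3 0.159, triamcinolone replicates 3 0.131 and 5 0.224), both lost with the slide block. Erythroid genes, 25 measured, were lower with 50 nM triamcinolone (-0.18, -0.08 and 0.14, adjusted p = 0.0393, 3 fell adjusted over the list alone, lost with the slide block, controls 3 0.17 and 4 0.133, triamcinolone replicates 3 0.105 and 5 0.295). Epidermal genes, 34 measured, were higher with 5 nM triamcinolone (0.06, 0.07 and 0.05, adjusted p = 0.0163, triamcinolone replicate 1 0.132). No member of these 3 lists was called in these contrasts. The interrenal axis (15 measured, lowest adjusted p = 0.205), pituitary and thyroid hormones (29, 0.217), lipid transport (55, 0.217) and hatching gland and yolk genes (13, 0.332) passed nowhere. Of these, 1 lipid gene was called, fads2, a fatty acid desaturase chosen after its values were seen, which rose by 0.54 with 5 nM triamcinolone. Among the called lists the median, the mean and the test had the same sign.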

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

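The tests of the clock pattern were chosen after the result was seen, unlike those of the early slides, pancreas genes and other splits.

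4 genes had a single array far from the rest of its group by Dixon's test. The period gene per1a read 0.13 on 50 nM triamcinolone replicate 1 (0.94 to 1.22 on the other 4 arrays), and the receptor target klf9 read -0.83 on 5 nM triamcinolone replicate 3 (-0.32 to -0.18). The hormone precursor pomca read -2.17 on 50 nM dexamethasone replicate 2 (-0.81 to -0.27), and the protease mmp9 0.61 on 5 nM dexamethasone replicate 4 (-1.33 to -0.83). These are 4.4% of the 91 groups tested over 13 measures, and chance flags about 1 in 20 groups. The dose response of klf2a differed between compounds (F = 31.3), a call lost with the slide block, normexp or the mean of probes. Prednisolone and triamcinolone doses share no slide.

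Circadian clock genes differed between dexamethasone and triamcinolone, with 13 of the 33 list members higher and 5 lower at 50 nM. The slide is argued against at 50 nM, where both groups lie on the same 5 slides and an offset cancels, and at 5 nM, where the difference within the 2 slides that hold both groups followed that at 50 nM with a slope of 1.02 ± 0.09, although 14 of 18 called genes kept their call with the slide as a block. Equal receptor activation cancels between compounds, and unequal stays open. Receptor targets outside the clock list cannot decide: at 50 nM their mean had no clear rise with dexamethasone (0.05, -0.10 to 0.20). Triamcinolone had an upper bound of -0.04 (adjusted p = 0.0794). A different hour of sampling for each compound may account for the pattern: the differences at 5 nM followed those at 50 nM with a slope of 0.98 ± 0.06, and 30 of 33 had the same sign. An effect of the compounds that is already full at 5 nM would give the same slope, no label gives the hour, and the explanations remain open.

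Genes called in the mean of the compounds could follow the slides, since all controls lie on slides 1 to 4. Among treated arrays 41.2% of the 85 genes at 50 nM and 66% of the 53 at 5 nM differed between later and control-bearing slides in the direction of the call, but each dose shares slides with only 2 of the 4 controls, so the bound set beforehand misses an offset of the other 2 and the slide stays open at both doses. With the slide as a block 17 and 35 of these genes kept their call. Treatment stays open as well: of the 100 genes with the smallest p on later slides, 74% kept their direction on the slides of the other 2 controls at 50 nM and 68% at 5 nM. Of 16 placements of the control label, 2 and 4 gave a share as high, with 84% and 88% as the highest of the others.

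Exocrine pancreas genes varied within groups: the mean of the 24 genes ran from -0.04 to 3.53 among the 5 arrays of 50 nM prednisolone and from 0.81 to 2.25 among those of 5 nM dexamethasone. It followed the first principal component with r = 0.97. The slide took 23.9% of the variance within groups (permutation p = 0.605), which argues against it as the main cause. Signal strength stays open, at r = 0.37 (p = 0.0449), rank correlation 0.29 (p = 0.125) and r = 0.24 without the 2 farthest arrays. No biological explanation was tested, since the labels give neither feeding nor stage of each pool.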

How the results depend on the processing

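Fits by scan day, without the noisiest or dimmest arrays or with the first principal component were chosen after the data were seen. Of 7621 comparisons of the 287 named gene results with an alternative or a left-out array, 7048 kept their direction and side of the threshold, 500 no longer passed, 68 newly passed and 5 reversed. Of 1260 comparisons of the 50 called lists, 859 stayed, 392 no longer passed and 9 reversed. A result counts as reversed when either value passed its test and the signs differ. In each paragraph below, values not given stayed within 1.5 times the count of the report, groups without further words are set against control, D, P and T stand for dexamethasone, prednisolone and triamcinolone, and the cause was not tested unless stated.

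With normexp correction the median change of all genes was -0.21 for 50 nM dexamethasone, and changes should be read against that shift. Counts were 35 (D), 15 (P) and 88 (T) at 50 nM, 64, 15 and 38 at 5 nM, 6 and 16 for the 50 and 5 nM means, 0 between prednisolone doses, 107 (D and P), 176 (D and T) and 11 (T and P) at 50 nM, 60, 173 and 10 at 5 nM, 1 gene shared at 5 nM, 0 interactions and 92 lists. Reversed were dapp1 (-0.03, 50 nM dexamethasone), rorcb (-0.10, 50 nM prednisolone, and -0.13 in the 50 nM mean), cry3b (-0.17, 50 nM triamcinolone), cyp2k6 (-0.11 in the 50 nM mean), and cartilage (adjusted p = 0.606 and 0.648, 50 nM prednisolone and triamcinolone), heat shock (0.614, 50 nM prednisolone) and cell cycle genes (0.554, 5 nM dexamethasone).

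Quantile normalization gave 88 genes for 50 nM and 70 for 5 nM prednisolone, 100 for the 5 nM mean, 3 between prednisolone doses, 1 shared at 50 nM and 2 interactions. The authors' table gave 34, 210 and 376 genes at 50 nM (D, P, T), 11 (P) and 529 (T) at 5 nM, 0 between prednisolone doses, 1274 (D and P), 1183 (D and T) and 63 (T and P) at 50 nM, 100, 645 and 311 at 5 nM, and reversed the photoreceptor list at 50 nM dexamethasone (adjusted p = 0.585).

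Without the filter on dim probes 1 gene was shared at 5 nM. With probes well above background on all arrays, which tests fewer genes, there were 54 for 5 nM prednisolone, 48 for the 50 nM mean and 2 between prednisolone doses. The mean of probes gave 53 for 5 nM prednisolone and 0 interactions, and reversed the cell cycle list at 50 nM dexamethasone (adjusted p = 0.769). With an estimated correlation 0 lists passed camera, against 50.

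The replicate number as a block gave 74 genes for 5 nM prednisolone, 149 for the 5 nM mean, 1 between dexamethasone doses, 2 shared at 50 nM and 6 at 5 nM, and 3 interactions. No label says that a number marks a clutch or day. The 50 nM groups share a slide by number, and others only in part. Centred per gene, same-number arrays of different groups had a median r of 0.03 (99 pairs, -0.62 to 0.74, 44 above 0.1), and 11 of 34 fitted their own number best. Receptor target means then passed (adjusted p = 0.0476) at -0.21 for 50 nM triamcinolone, 0.16 (D minus P), 0.28 (D minus T) and -0.12 (T minus P) at 50 nM and 0.20 (D minus T) at 5 nM.

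The slide as a block gave 42, 34 and 135 genes at 50 nM (D, P, T), 60 for 5 nM prednisolone, 22 and 117 for the 50 and 5 nM means, 3 and 0 between dexamethasone and prednisolone doses, 646 (D and P), 664 (D and T) and 49 (T and P) at 50 nM, 74 (T and P) at 5 nM, 0 interactions and 33 lists. The photoreceptor list at 50 nM dexamethasone reversed (adjusted p = 0.995), and receptor target means passed (adjusted p = 0.0397) at -0.21 for 50 nM triamcinolone, 0.16 (D minus P) and 0.28 (D minus T). Centred arrays sharing a slide had a median r of 0.10 (47 pairs). With the scan day as a block there were 75 (P) and 513 (T) at 5 nM, 39 and 104 for the means, 1 and 8 between dexamethasone and prednisolone doses, 589 (D and P) and 574 (D and T) at 50 nM, 365, 780 and 73 (T and P) at 5 nM, 5 shared at 5 nM and 2 interactions.

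Fits of only the groups compared, with fewer arrays, gave 11, 5 and 49 genes at 50 nM (D, P, T), 41, 1 and 33 at 5 nM, 29 for the 5 nM mean, 0 between prednisolone doses, 64 (D and P), 158 (D and T) and 12 (T and P) at 50 nM, 61, 233 and 4 at 5 nM, and 1 shared at 5 nM. Array weights gave 2385, 130 and 505 at 50 nM, 398 (D) and 3340 (T) at 5 nM, 604 and 467 for the means, 138 and 460 between dexamethasone and triamcinolone doses, 1591, 1476 and 69 (T and P) at 50 nM, 323, 2764 and 411 at 5 nM, 23 shared at 50 nM and 10 interactions.

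With the first principal component as a covariate counts were 452, 569 and 1181 at 50 nM (D, P, T), 433, 173 and 1223 at 5 nM, 1131 and 535 for the means, 3, 4 and 7 between doses, 871, 790 and 99 between compounds at 50 nM, 604, 854 and 80 at 5 nM, 38 and 19 shared at 50 and 5 nM, and 3 interactions. Of 50 called lists 22 no longer passed. The exocrine pancreas (50 nM dexamethasone, adjusted p = 0.903) and xenobiotic lists (5 nM prednisolone, 0.316) reversed. Without the noisiest array (61.6% of probes well above background) there were 80 genes for the 5 nM mean, 1 between D doses, 1 between T doses and 1 shared at 50 nM. Without both dim arrays there were 56 for 5 nM prednisolone, 148 for the 5 nM mean, 2 between dexamethasone doses, 19 (T and P) at 5 nM, 1 shared at 50 nM and 2 interactions.

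Leaving out 1 array at a time, with its effect by array in the report, the counts ran from 31 to 78, 19 to 79 and 117 to 247 at 50 nM (D, P, T), 76 to 158, 20 to 53 and 163 to 341 at 5 nM, 12 to 148 and 29 to 80 for the means, 0 to 3, 0 to 28 and 0 to 2 between doses, 164 to 299 (D and P), 239 to 382 (D and T) and 20 to 34 (T and P) at 50 nM, 110 to 169, 300 to 457 and 22 to 48 at 5 nM, 0 to 3 and 1 to 3 shared at 50 and 5 nM, 1 to 2 interactions and 38 to 65 lists. Receptor target means against control ran from 0.00 to 0.08, -0.15 to -0.08 and -0.27 to -0.20 at 50 nM and 0.02 to 0.11, -0.06 to 0.02 and -0.18 to -0.09 at 5 nM. Between doses they ran from -0.05 to 0.02, -0.12 to -0.05 and -0.14 to -0.05. Between compounds they ran from 0.13 to 0.18, 0.25 to 0.30 and -0.14 to -0.10 at 50 nM and 0.05 to 0.13, 0.16 to 0.25 and -0.16 to -0.07 at 5 nM.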

Other observations

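Some photoreceptor genes, chosen after their values were seen, differed between compounds, between which the list was not tested. The cone arrestin arr3a was 1.01 log2 higher with dexamethasone than with triamcinolone at 50 nM (adjusted p = 5.73e-05), the opsin kinase grk7a 1.23 (adjusted p = 2.83e-05), the cyclase activator guca1aa 1.09 (adjusted p = 0.00286) and the visual cycle gene rpe65a 1.00 (adjusted p = 9.86e-05), and 7 of 43 list members were higher and 2 lower in all.

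Splits of the arrays (100 for each comparison, the real one included) were fitted alike. For 50 nM dexamethasone, prednisolone and triamcinolone against control 1 of 100 splits, the real one, gave as many genes: 67 against at most 56, 57 against 10 and 222 against 64. At 5 nM it was again 1 for each compound: 142 against 52, 35 against 24 and 265 against 227. The split with 56 genes put the arrays of slides 1 and 2 against the rest, and a split by slides 3 and 4, not among the 100, called 293 genes at 5 nM dexamethasone, above the real 142, and 137 at 5 nM triamcinolone, but 0 at 5 nM prednisolone; by slides 1 and 2 it called 0 at 50 nM prednisolone and triamcinolone. With the slide as a block dexamethasone had 42 genes at 50 nM and 141 at 5 nM. In the 50 nM mean 3 of 100 splits called at least 85 genes, and in the 5 nM mean 1 called at least 53 (highest other 30). The chance of a random split giving these counts is under 0.05 in each case, which does not exclude the slides.

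Some splits called far more genes than the real one, which points to a structure of the samples. The highest other counts were 8215 for the 50 nM mean, 6522 for dexamethasone against prednisolone at 50 nM (297 real, 3 of 100 splits as large), 6653 for triamcinolone against prednisolone at 50 nM (32 real, 4 of 100) and 166 at 5 nM (33 real, 3 of 100). Dexamethasone against triamcinolone reached 333 at 50 nM and 404 at 5 nM with at most 75 and 5 in other splits, and dexamethasone against prednisolone at 5 nM 167 with at most 2 (1 of 100 each). Between prednisolone doses chance was not excluded, since 6 of 100 splits gave at least its 1 gene (highest other 3134). A count of 0 is reached by every split, 100 of 100, so the splits say nothing about the 0 genes between dexamethasone doses (highest other 1967), between triamcinolone doses (1) and shared by all 3 compounds at 50 nM (0). The genes shared at 5 nM numbered 3, reached by 1 split (highest other 1). The interaction's 1 gene was reached by 2 of 100 splits (highest other 1).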
